A study of Mus musculus with 24 samples.

How the data were processed

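RNA from 3 B cell populations sorted from mouse bone marrow was measured in 24 libraries. Every mouse carried 1 copy of Mb1-Cre, a recombinase expressed in B lineage cells. 4 mice had both Vhl alleles flanked by lox sites (flox/flox) and 4 had 1 such allele (flox/WT), so the controls also carried the recombinase. Each mouse gave 1 library of a combined pro-B and pre-B sort (called proBpreB, as labelled), 1 of immature and 1 of mature B cells. The labels give the population names but not the surface markers of the gates.

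Libraries were made with the SMARTer Universal Low Input RNA Kit from RNA of cells sorted into lysis buffer, per the labels' protocols. The tools named in the submitters' processing notes are CASAVA, FastQC, Trim Galore, HISAT2, featureCounts and DESeq2, with the build mm10 (GRCm38). Their versions, settings and order, the gene annotation and any use of strand are not given in the sources used here, so reads of overlapping or antisense genes cannot be told apart. The authors deposited raw counts for 24421 genes by symbol, and a table of normalised signal for 17514 genes. The deposited signal equals the counts divided by 1 factor per library, and these factors equalled median-of-ratios size factors recomputed from the counts to within a relative difference of 2.67e-15. Tests used the deposited counts alone. Columns were matched to samples by the running number that opens each sample title. The count table held 0 immunoglobulin or T cell receptor segments and 0 mitochondrially encoded genes, so those were not analysed here.

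Totals ran from 7850186 to 11863949 counts per library, and a limit of 3 counts corresponded to 0.253 to 0.382 CPM, the count scaled to the library total. Where a group had 0 counts, a fold change is given as a lower bound against 3 counts over the 4 libraries of the group. With 1 to 3 counts in a group, the ratio of summed counts is given with an exact 95% binomial interval. PCR copies were not marked by molecular identifiers, so these limits cover counting error only. To look for a repeat deposit of a library, counts of libraries of a group were compared. The lowest chi-square per degree of freedom was 6.40, a spread that includes differences between mice, and no pair was counted as 1 library.

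Counts were tested with edgeR 4.0.16 in R 4.3.3 (TMM scaling, filterByExpr on the 6 groups, robust quasi-likelihood fit). One fit held all 24 libraries, which left 18 residual degrees of freedom and 12850 genes. P-values were adjusted by the Benjamini-Hochberg method within each of 10 comparisons at a threshold of 0.05, 3 between genotypes, 4 between stages and 3 of the difference between genotype effects. Values per group are means ± SD of TMM-scaled CPM over 4 mice, and log2 fold changes are edgeR estimates with SE. Vhl was also tested by a two-sided exact permutation test of log2 CPM over the 70 assignments. Before the data were examined, 25 gene lists were fixed. Some lists share members. Egln1 and Egln3 are among both the HIF pathway components and the other hypoxia genes, and Pfkfb4 is in the glycolysis list and in the latter. The immunoglobulin lambda and mitochondrial lists had 0 members in the table, and 23 lists were tested in 3 genotype comparisons, a family of 69 tests. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01 on log2 CPM (prior count 2), with camera at an estimated correlation and with fry beside it. Camera tests a list against the other genes and fry tests it against no change, so their calls answer different questions. For the 3 differences between populations the lists formed a second family.

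Named genes followed a rule fixed in advance. For a genotype comparison it took Vhl, then the 12 largest rises and 12 largest falls among genes past the threshold with a mean log2 CPM of at least 2 and no overlap between genotypes, without unnamed clone symbols, then up to 4 passing members of each list. Stage comparisons took 8 in each direction, and differences between populations the 8 smallest adjusted p-values. Pfkfb4, the glycolysis member without a call, was named after its values were seen. Some genes that the rule named are not reported here. Gene positions came from the RefSeq table of GRCm38, in which 12174 of the 12850 tested symbols matched.

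The populations of 1 mouse share that mouse, so the stage comparisons are paired by animal. Deviations from the group means of libraries of the same mouse correlated at -0.284 to 0.276 over the 5000 genes used, 8 of 16 exceeded 0.1, and 7 were the highest for their own mouse. In an alternative edgeR fit the mouse was a block for the stages and the differences between populations, and the replicate number for the genotype comparisons, since a mouse has 1 genotype. Other alternatives, fixed in advance, were RLE size factors, no expression filter, a filter of 10 CPM in 4 libraries, only the groups compared, DESeq2 1.42.0, limma-voom with the mouse as a random block (consensus correlation 0.0872) and leaving out each of the 8 mice. Sex of the mouse as a covariate was added after seeing that replicate 1 of each genotype had Y-linked counts above Xist.

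The scripts were tested on simulated counts with 200 changed genes per run. For the genotype comparison, 98.5% of 4-fold changes were recovered in proBpreB, 92.4% in immature and 93.9% in mature cells, and 77.6%, 71.6% and 67.2% of 2-fold changes. At 1.5-fold the shares were 35.8%, 35.8% and 28.4%, so small changes were often missed in the simulation. With 200 changed genes the simulated comparisons called fewer genes than the real ones, which made the adjusted threshold stricter. The shares therefore do not measure what the real comparisons missed. For the difference between immature and proBpreB effects, 83.3% of 4-fold and 16.4% of 1.5-fold changes were recovered. The shares at 1.5-fold were 16.4% for mature against immature and 7.46% for mature against proBpreB effects. False calls made up 3 of 144, 8 of 141 and 5 of 131 calls between genotypes and 9 of 113, 6 of 105 and 4 of 94 calls for the differences, in the same order. For immature against proBpreB and mature against immature cells they made up 6 of 131 and 5 of 132 calls in flox/WT and 11 of 136 and 5 of 128 in flox/flox mice, so some comparisons exceeded the nominal 5%.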

Results

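Gene expression was measured in 3 B cell populations from the bone marrow of 8 mice, 4 flox/flox and 4 flox/WT for Vhl, the subunit of the ubiquitin ligase that marks hypoxia-inducible factor (HIF) for destruction. Each of the 6 groups held 4 libraries from 4 mice. Library totals lay between 7850186 counts in immature flox/flox replicate 2 and 11863949 in immature flox/WT replicate 3. The design compares the genotypes within each population, which asks what differs between B cells of mice with both and with 1 floxed Vhl allele, the populations within each genotype, and the genotype effect between populations.

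Vhl, on chromosome 6 at 113623994 to 113631634 (GRCm38), was lower in flox/flox than in flox/WT libraries of every population. In proBpreB cells it measured 10.2 ± 3.37 CPM in flox/flox and 25.3 ± 2.02 CPM in flox/WT mice (SD, n = 4 each; two-sided exact permutation p = 0.0286). In immature cells the values were 5.58 ± 2.31 and 35.5 ± 8.88 CPM, and in mature cells 7.60 ± 1.90 and 29.1 ± 2.81 CPM (exact permutation p = 0.0286 for each, n = 4 per group). That p is the smallest that 4 against 4 libraries can give. The flox/flox means were 40.1%, 15.7% and 26.1% of the flox/WT means, and no flox/flox library reached a flox/WT library of its population. The position of the lox sites in the gene is not given in the sources used here, so counts over the whole gene do not measure the deleted part alone.

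**Figure D1:**
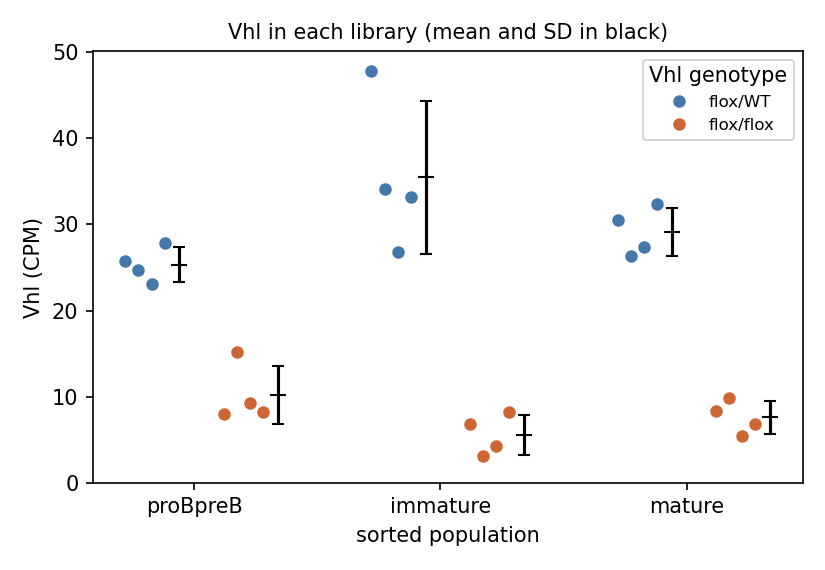
Vhl in CPM (y axis, from 0) for each library of the 3 populations (x axis), with flox/WT in blue, flox/flox in orange, and mean and SD of 4 mice in black. The flox/flox libraries lie between 3.07 and 15.1 CPM and the flox/WT libraries between 23.0 and 47.9 CPM.

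In proBpreB cells, glycolytic enzymes and other hypoxia-response genes rose in flox/flox mice. Ak4, a mitochondrial adenylate kinase on chromosome 4 at 101416478 to 101467771, rose from 0.196 ± 0.200 to 115 ± 9.75 CPM, a log2 change of 9.10 (SE 0.30, adjusted p = 1.88e-19). Slc16a3, a lactate and proton exporter, rose from 7.50 ± 1.73 to 355 ± 32.9 CPM, and Bnip3, a mitophagy receptor, from 45.2 ± 6.14 to 1126 ± 53.0 CPM. Of the list of HIF-driven glycolysis, 19 of 20 measured genes rose (19 adjusted over the list alone), with a median log2 change of 3.05. Among them Tpi1 rose by 3.97, Aldoa by 3.46 and Ldha by 3.08 on the log2 scale, while Pfkfb4 measured -0.12 and did not pass. Of the other hypoxia genes, 23 of 29 rose (23 adjusted over the list alone, median 2.18), including Egln3, the oxygen-sensing prolyl hydroxylase, by 4.45 and the collagen hydroxylase Plod2 by 4.63. By limma's camera the adjusted p was 2.73e-79 for glycolysis and 5.06e-56 for the other hypoxia genes, and with an estimated correlation 1.71e-06 and 3.43e-11. Counting all genes, 434 rose and 354 fell of 12850 tested. The falls numbered 209 and 192 without flox/flox replicates 1 and 4 and 162 without flox/WT replicate 4, where the rises numbered 329, 312 and 304.

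Genes that fell in proBpreB cells included Col5a3, a collagen chain, which went from 294 ± 124 to 36.1 ± 6.30 CPM (log2 change -3.03, SE 0.32, adjusted p = 7.83e-07), and Ms4a1, which encodes CD20, from 143 ± 32.5 to 41.6 ± 15.3 CPM. Of the mature B cell list, 12 of 21 fell and 2 rose (14 and 2 adjusted over the list alone, median -0.54), with Klf2, a regulator of lymphocyte trafficking, at -0.88, the homing receptor Ccr7 at -0.82, and Ltb, a lymphotoxin chain, up by 1.10. Camera gave an adjusted p = 2.88e-08 for this list, and an adjusted p = 0.0533 with an estimated correlation. B cell receptor signalling genes fell in 8 of 23 cases and rose in 0 (10 and 0 adjusted over the list alone, median -0.23), with Cd79b at -0.83 and Cd79a at -0.59; adjusted p = 7.14e-05, and adjusted p = 0.118 with an estimated correlation. The receptor tyrosine kinase gene Ret had a log2 change of -1.98 with an edgeR adjusted p of 0.0102, which was 0.0542 without flox/WT replicate 4.

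Other lists that passed camera in proBpreB cells had medians from -0.26 to 0.51. Nuclear oxidative phosphorylation genes had a median of -0.19, with 2 of 30 lower (4 adjusted over the list alone; adjusted p = 7.50e-05, adjusted p = 0.409 with an estimated correlation, and 0.0619 by fry). Tricarboxylic acid cycle genes had a median of -0.12, with 0 of 20 passing and 2 lower adjusted over the list alone (adjusted p = 0.0296, and adjusted p = 0.371 with an estimated correlation). That call was also lost without flox/flox replicate 2 (adjusted p = 0.0740), flox/flox replicate 3 (0.0507), flox/WT replicate 1 (0.169) or flox/WT replicate 2 (0.112), and with the filter of 10 CPM (0.0857). Immediate early and heat shock genes had 4 of 19 lower (7 lower and 1 higher adjusted over the list alone, median -0.26, adjusted p = 0.0415, and adjusted p = 0.315 with an estimated correlation). This call ended without flox/flox replicate 2 (adjusted p = 0.0807) or 4 (0.0700), or flox/WT replicate 1 (0.0695), 2 (0.0903) or 4 (0.0608), and with the sex of the mouse as a covariate (0.0528), a setting chosen after seeing the data. Natural killer cell markers had a median of 0.51 with 0 of 10 passing (0 adjusted over the list alone; adjusted p = 0.0296, and adjusted p = 0.167 with an estimated correlation), lost without flox/flox replicate 2 (0.108), flox/WT replicate 1 (0.0568) or 4 (0.0542). Erythroid markers had a median of 0.51 with 0 of 13 passing (0 adjusted over the list alone; adjusted p = 0.0171, adjusted p = 0.493 with an estimated correlation, and 0.142 by fry), lost without flox/flox replicate 2 (0.0539) or 3 (0.0694), or flox/WT replicate 3 (0.0642). The proliferation list had a median of 0.06 with 0 of 25 passing (0 adjusted over the list alone), and pro-B and pre-B genes a median of 0.10 with 1 of 20 lower (1 adjusted over the list alone). The remaining lists did not pass. Their medians were 0.01 for HIF pathway components, -0.18 for the Bcl2 family, -0.13 for trafficking and adhesion, -0.02 for cholesterol synthesis, 0.08 for the interferon response and -0.04 for the unfolded protein response. Marker lists had 0.54 for T cells, 0.08 for neutrophils and monocytes, -0.13 for plasma cells, 0.48 for plasmacytoid dendritic cells, -0.20 for stroma and endothelium and 0.14 for sex-linked genes. In flox/WT mice the natural killer list had a mean of 4.02 log2 CPM in proBpreB, 0.30 in immature and 0.67 in mature cells. For plasmacytoid dendritic cell markers the means were 6.21, 3.78 and 3.51. The proBpreB sort thus held more of these transcripts, and whether other cells in it gave them was not tested.

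**Figure D2:**
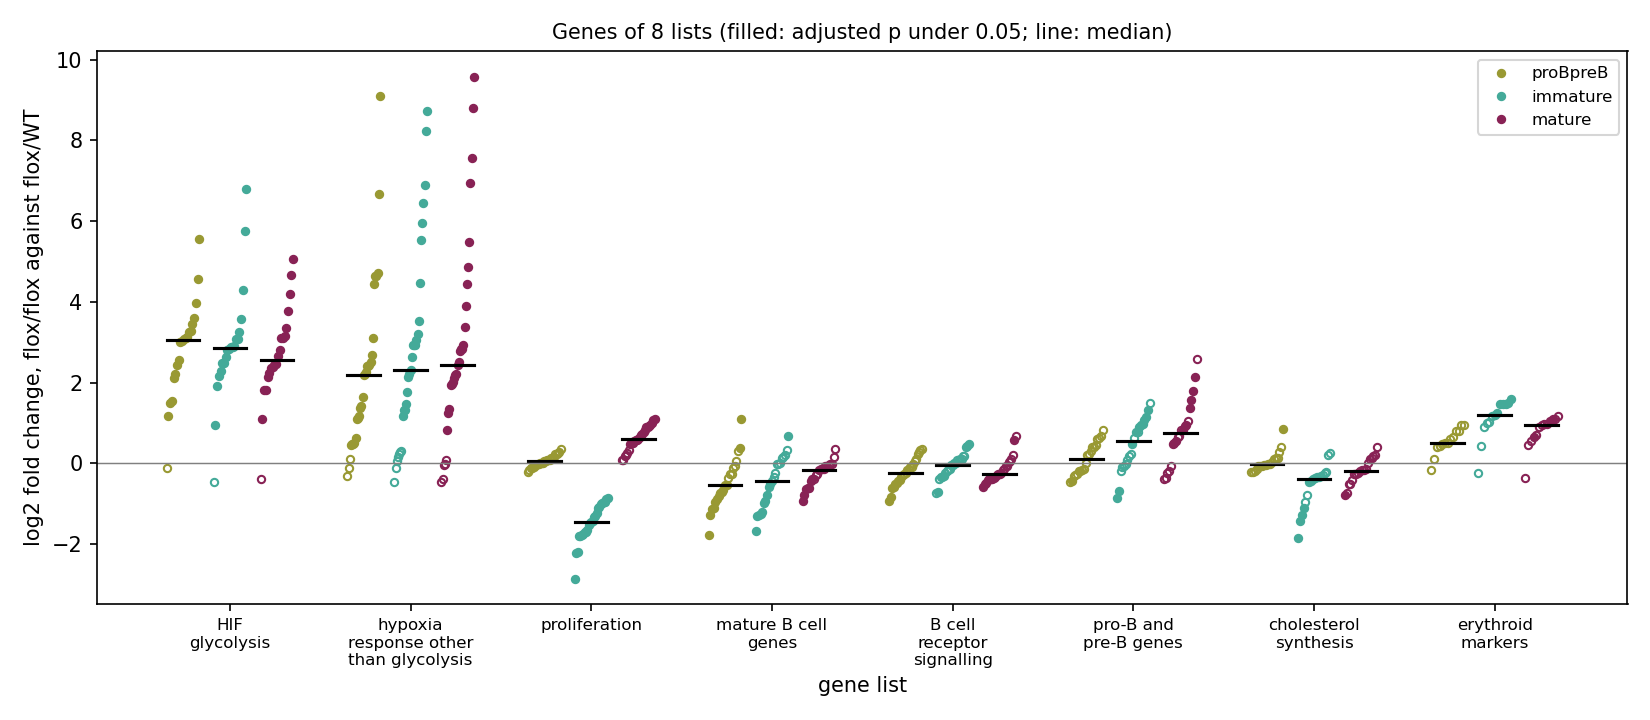
Log2 fold change of flox/flox against flox/WT (y axis) for each measured gene of 8 lists (x axis) in the 3 populations (colours); filled points passed an adjusted p of 0.05 and lines mark medians. Glycolysis medians lie at 3.05, 2.85 and 2.55, and proliferation medians at 0.06, -1.45 and 0.60.

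In immature cells the same hypoxia lists rose. Vldlr, a lipoprotein receptor on chromosome 19, had 0 counts in flox/WT and 90.0 ± 6.60 CPM in flox/flox mice, at least 1157-fold higher. Aldoc, an aldolase, rose from 3.06 ± 0.924 to 353 ± 13.8 CPM (log2 change 6.81, SE 0.17, adjusted p = 1.73e-22), and Bnip3 from 20.1 ± 3.38 to 1243 ± 115 CPM. Of the glycolysis list, 19 of 20 rose (19 higher and 1 lower adjusted over the list alone, median 2.85, camera adjusted p = 2.81e-45, and 6.08e-05 with an estimated correlation). Other hypoxia genes rose in 22 of 29 cases (23 higher and 1 lower adjusted over the list alone, median 2.30, camera adjusted p = 2.60e-36, and 5.25e-10 with an estimated correlation), with Vegfa, the vascular growth factor, up by 5.53 and Egln3 by 6.44 on the log2 scale. The median is the same with the gene of this list at 0 counts in a group set at its bound. Over all genes, 1310 rose and 1346 fell.

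All 25 genes of the proliferation list fell in immature flox/flox cells (25 adjusted over the list alone, median log2 change -1.45). Camera gave an adjusted p = 1.36e-25, and an adjusted p = 0.0533 with an estimated correlation of 0.60 between its genes. Mki67, the Ki-67 proliferation antigen on chromosome 7 at 135689784 to 135716450, went from 216 ± 124 to 29.6 ± 13.1 CPM (log2 change -2.86, SE 0.50, adjusted p = 0.000304), the spindle motor Kif11 from 159 ± 31.4 to 34.1 ± 8.86 CPM, and Birc5 (survivin) from 98.4 ± 16.3 to 28.7 ± 3.07 CPM. The kinetochore gene Cenpf fell by 2.73 on the log2 scale. Erythroid markers moved in the same libraries, with 7 of 13 higher (10 adjusted over the list alone, median 1.21, adjusted p = 0.000415, and adjusted p = 0.315 with an estimated correlation), among them Car2 at 183 ± 9.66 against 77.6 ± 10.4 CPM. The near-identical globin pairs Hba-a1 and Hba-a2, and Hbb-bs and Hbb-bt, are uncertain because reads can be split between copies or counted for each. Hba-a1 and Hba-a2 had equal counts in 21 of 24 libraries. They are not separate results, so counts of changed erythroid genes can overstate them. Neutrophil and monocyte markers had 5 of 19 higher (5 adjusted over the list alone, median 0.50, adjusted p = 0.00369, and adjusted p = 0.409 with an estimated correlation), with S100a8 at 2847 ± 432 against 1532 ± 190 CPM.

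Of the mature B cell list, 10 of 21 genes fell and 1 rose in immature flox/flox cells (11 and 2 adjusted over the list alone, median -0.44, adjusted p = 0.000481, and adjusted p = 0.247 with an estimated correlation). H2-Eb1, an MHC class II chain, went from 1021 ± 81.7 to 318 ± 50.3 CPM. Cholesterol synthesis genes fell in 7 of 18 cases (9 adjusted over the list alone, median -0.38, adjusted p = 4.37e-05, and adjusted p = 0.118 with an estimated correlation), with Sqle, squalene epoxidase, at -1.85 and Idi1 at -1.27. Pro-B and pre-B genes had 7 of 20 higher and 2 lower (7 and 2 adjusted over the list alone, median 0.55, adjusted p = 0.0296, and adjusted p = 0.377 with an estimated correlation), with Cd93 at 1.07 and Lef1 at -0.68. This call was lost without flox/flox replicate 4 (adjusted p = 0.0806), flox/WT replicate 1 (0.0568) or 2 (0.0937). Tricarboxylic acid cycle genes fell in 5 of 20 cases (5 adjusted over the list alone, median -0.16, adjusted p = 0.0108, and adjusted p = 0.315 with an estimated correlation), with Idh3a at -0.50. Within the Bcl2 family, which did not pass as a list (median -0.15; 6 of 15 lower and 2 higher, the same counts adjusted over the list alone), Bcl2, an inhibitor of cell death, was at -1.33 and Bcl2l11, which encodes the pro-apoptotic Bim, at 1.24. Also not passing, with their medians, were HIF pathway components (0.04), oxidative phosphorylation (-0.07), B cell receptor signalling (-0.04), trafficking and adhesion (-0.03), the interferon response (-0.32), the unfolded protein response (0.02) and immediate early and heat shock genes (-0.02). The marker lists without a call had medians of 0.22 for T cells, 0.53 for natural killer cells, -0.08 for plasma cells, 0.02 for plasmacytoid dendritic cells, 0.52 for stroma and endothelium and -0.16 for sex-linked genes.

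In mature cells the hypoxia lists rose. Mgarp, a mitochondrial protein gene on chromosome 3, had 0 counts in flox/WT and 131 ± 9.75 CPM in flox/flox mice, at least 1522-fold higher. Vldlr had 1 count in flox/WT and 3469 in flox/flox libraries, a ratio of 3350 (95% counting interval 601 to 132340). Egln3 rose from 1.41 ± 0.404 to 176 ± 17.9 CPM (log2 change 6.95, SE 0.18, adjusted p = 8.76e-22). Of the glycolysis list, 19 of 20 rose (19 higher and 1 lower adjusted over the list alone, median 2.55, camera adjusted p = 2.11e-48, and 4.63e-05 with an estimated correlation), and of the other hypoxia genes 23 of 29 (23 higher and 1 lower adjusted over the list alone, median 2.44, adjusted p = 1.98e-42, and 2.04e-10 with an estimated correlation). HIF pathway components had 4 of 13 higher and 1, Vhl, lower (4 and 1 adjusted over the list alone, median 0.14, adjusted p = 0.00550, and 0.0358 with an estimated correlation), with Egln1 up by 2.94. With the filter of 10 CPM that adjusted p was 0.0816. Egln1 and Egln3 are also members of the other hypoxia genes, so the call for HIF pathway components is not separate from theirs. Over all genes, 1245 rose and 851 fell, or 1296 changed in place of 2096 when only the mature libraries were fitted. The falls numbered 514 without flox/flox replicate 3.

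Of the proliferation list, 16 of 25 genes rose in mature flox/flox cells (18 adjusted over the list alone, median log2 change 0.60; adjusted p = 6.90e-08, and adjusted p = 0.315 with an estimated correlation). Rrm2, a ribonucleotide reductase subunit, went from 56.7 ± 20.6 to 119 ± 27.9 CPM and Ccnb2, cyclin B2, from 18.7 ± 5.00 to 35.7 ± 5.70 CPM. Erythroid markers had 3 of 13 higher in the same libraries (4 adjusted over the list alone, median 0.96, adjusted p = 0.00550, and adjusted p = 0.409 with an estimated correlation). Natural killer cell markers had 3 of 10 higher (4 adjusted over the list alone, median 0.94, adjusted p = 0.0296, and adjusted p = 0.167 with an estimated correlation), with Prf1, perforin, up by 2.00. The list call was at 0.0503 without flox/WT replicate 1. The level of this list was low, with a mean of 0.67 log2 CPM in flox/WT and 1.44 in flox/flox libraries. Pro-B and pre-B genes had 7 of 20 higher (11 higher and 1 lower adjusted over the list alone, median 0.76, adjusted p = 0.00163, and adjusted p = 0.242 with an estimated correlation). Lef1, a lymphoid transcription factor, went from 16.5 ± 1.93 to 73.2 ± 10.5 CPM, and Igll1, the surrogate light chain, from 6.90 ± 2.80 to 23.8 ± 6.96 CPM. The 16 list members at 10-fold or more in proBpreB cells implied a median share of 2.07% of such cells in this sort. Lef1 implied 23.5% and Igll1 2.75%, and 3 of the 16 implied a share below 0. For the list, such cells cannot be told apart from a change in mature cells.

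Genes that fell in mature cells included Sdc1, which encodes the plasma cell antigen syndecan-1 on chromosome 12 at 8771396 to 8793716 and went from 31.4 ± 7.02 to 5.66 ± 1.86 CPM (log2 change -2.48, SE 0.24, adjusted p = 6.26e-09), and Il5ra, the interleukin-5 receptor, from 42.8 ± 2.81 to 10.0 ± 4.55 CPM. Mature B cell genes fell in 7 of 21 cases (8 adjusted over the list alone, median -0.16, adjusted p = 0.00236, and adjusted p = 0.315 with an estimated correlation), with Ciita, the MHC class II transactivator, at -0.92 and H2-Ab1 at -0.63. B cell receptor signalling genes had 8 of 23 lower and 1 higher (11 and 1 adjusted over the list alone, median -0.27, adjusted p = 0.00336, and adjusted p = 0.251 with an estimated correlation), with Cd72 at -0.51 and Pik3ap1 at 0.58. Tricarboxylic acid cycle genes had 3 of 20 lower (3 adjusted over the list alone, median -0.18, adjusted p = 0.0131, and adjusted p = 0.315 with an estimated correlation), a call at 0.0558 without flox/WT replicate 1. Interferon response genes had 4 of 20 lower and 1 higher (5 and 1 adjusted over the list alone, median -0.38, adjusted p = 0.0386, adjusted p = 0.666 with an estimated correlation, and 0.288 by fry). This call ended with the filter of 10 CPM (0.162), and without flox/flox replicate 1 (0.0906) or 4 (0.0583), or flox/WT replicate 3 (0.0570) or 4 (0.125). In the Bcl2 family 5 of 15 rose (5 adjusted over the list alone, median 0.01), among them Bbc3 (Puma) by 1.49 and Bcl2 by 0.63, without a call for the list. Lists without a call had medians of -0.08 for oxidative phosphorylation, -0.09 for trafficking, -0.18 for cholesterol synthesis, -0.17 for the unfolded protein response and 0.22 for immediate early and heat shock genes. Markers without a call had 0.40 for T cells, 0.27 for neutrophils and monocytes, 0.09 for plasma cells, 0.04 for plasmacytoid dendritic cells, -0.02 for stroma and endothelium and 0.19 for sex-linked genes. The median, the mean and the test differed in sign only for lists without a call.

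**Figure D3:**
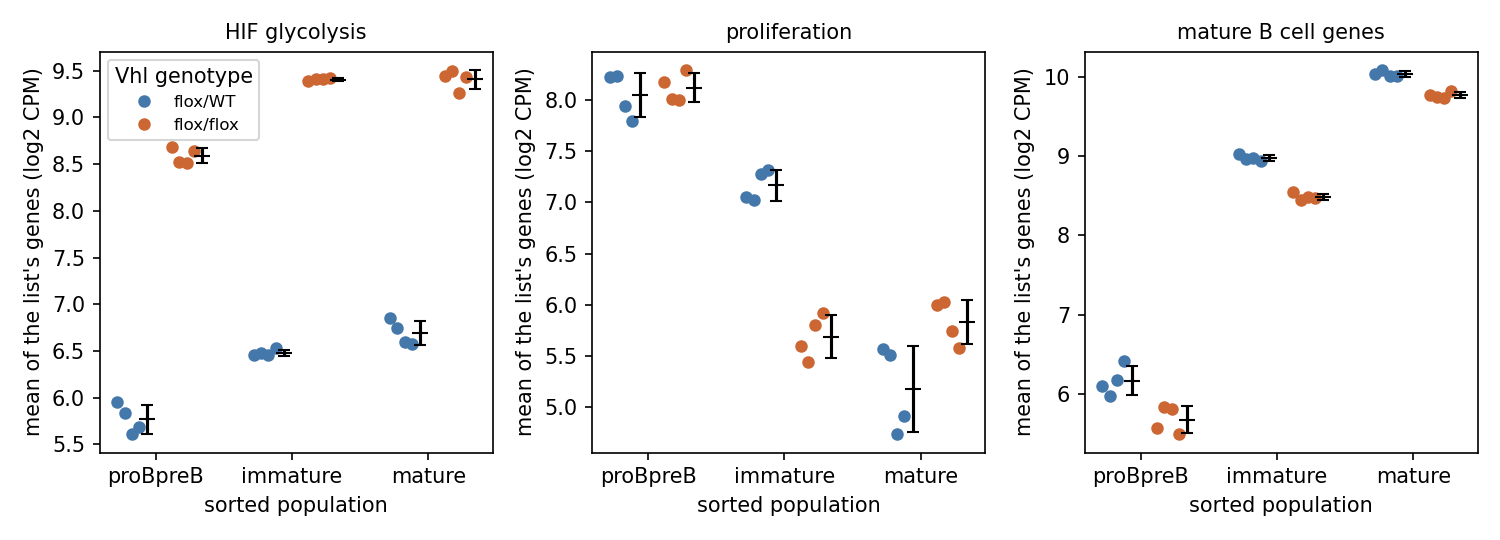
Mean log2 CPM of 3 lists (y axes) for each library of the 3 populations (x axis), with flox/WT in blue, flox/flox in orange, and mean and SD of 4 mice in black. For proliferation the immature means were 7.17 in flox/WT and 5.69 in flox/flox, and the mature means 5.18 and 5.83.

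Across populations, 246 genes rose in all 3 and 42 fell in all 3, where independent lists would share 4.29 and 2.46. The populations came from the same mice, but each comparison used its own libraries. Between immature and mature cells, 585 genes rose in both and 239 fell in both, against 127 and 89.1 for independent lists. Genes lower in immature and higher in mature flox/flox cells numbered 134, against 130, and those higher in immature and lower in mature cells 9, against 86.8.

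The genotype effect itself was compared between populations. Between mature and immature cells it differed for 995 genes, 708 of them with the higher value in mature cells. Ccnb2 differed by 2.64 on the log2 scale (SE 0.22, adjusted p = 2.37e-09). For proliferation all 25 genes passed upward (25 adjusted over the list alone), with a median difference of 2.15 and a camera adjusted p = 1.60e-40, or 0.0242 with an estimated correlation. Other hypoxia genes were 3 higher and 3 lower of 29 (5 and 4 adjusted over the list alone), with a median of -0.07 and no call (camera adjusted p = 0.967). Between immature and proBpreB cells it differed for 1395 genes, with all 25 proliferation genes lower in immature cells (25 adjusted over the list alone, median -1.54, adjusted p = 1.89e-27, and adjusted p = 0.0700 with an estimated correlation). Aldoc differed by 2.25 in the other direction. Between mature and proBpreB cells it differed for 393 genes, among them Ndrg1 by 3.03, Egln3 by 2.50 and Vegfa by 3.08. The flox/flox Vhl mean was 40.1% of the flox/WT mean in proBpreB, 15.7% in immature and 26.1% in mature cells. A smaller response in proBpreB cells thus cannot be told apart from less loss of Vhl there. Other hypoxia genes were 9 higher and 1 lower of 29 (10 and 3 adjusted over the list alone), with a median difference of 0.29 (camera adjusted p = 0.000413, and 0.00869 with an estimated correlation). These counts moved by over 1.5 times with a mouse left out. The first was 661 without flox/WT replicate 3. The second was 876, 833 and 805 without flox/flox replicates 1 and 4 and flox/WT replicate 4. The last was 261, 255, 254 and 255 without flox/flox replicates 1, 3 and 4 and flox/WT replicate 4, and 606 with DESeq2. The proBpreB genotype count was 504 without flox/flox replicate 4 and 466 without flox/WT replicate 4.

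Between stages in flox/WT mice, the genes that fell from proBpreB to immature cells included Vpreb1, a surrogate light chain gene, and those that rose included Ms4a1. Vpreb1 went from 345 ± 215 to 3.24 ± 0.744 CPM (log2 change -6.70, SE 0.41, adjusted p = 9.56e-12), and Dntt, terminal transferase, had a log2 change of -6.14. Ms4a1 rose from 143 ± 32.5 to 5097 ± 852 CPM, Cr2, the complement receptor, by 4.95 and Cxcr5, a follicle-homing receptor, by 4.87 on the log2 scale. In all, 3084 genes rose and 3266 fell. From immature to mature cells 2011 rose and 2196 fell, with Ccr6, a chemokine receptor, up from 6.90 ± 3.78 to 115 ± 15.2 CPM (log2 change 4.02, SE 0.24, adjusted p = 1.31e-12), Icosl, a costimulatory ligand, up by 3.30, and Ccnd2, cyclin D2, down from 487 ± 63.1 to 36.2 ± 11.7 CPM.

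In flox/flox mice the same steps called 7188 and 3411 genes. From proBpreB to immature cells 3688 rose and 3500 fell, with Ms4a1 up from 41.6 ± 15.3 to 5045 ± 276 CPM (log2 change 6.92, SE 0.23, adjusted p = 7.00e-19), Scd1, a fatty acid desaturase, up by 5.00, and Vpreb1 down from 427 ± 54.5 to 8.25 ± 4.34 CPM. From immature to mature cells 1663 rose and 1748 fell, with Il9r, the interleukin-9 receptor, up from 1.78 ± 0.82 to 89.7 ± 23.3 CPM (log2 change 5.63, SE 0.43, adjusted p = 5.00e-10), Ccr6 up by 5.24 and Pmaip1 (Noxa) up by 3.94, while Cox6a2, a cytochrome oxidase subunit, went from 57.5 ± 8.08 to 3.14 ± 1.66 CPM.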

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

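The 3 tests of cell mixtures in this part were chosen after the result was seen and revised after first outcomes, as stated beside each, while the counts over other splits of the mice were planned.

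The genotype effect on the following genes differed between populations by edgeR. Between mature and immature cells the log2 difference was 3.08 for 2810417H13Rik, 3.06 for Shcbp1, 2.85 for Esco2, 2.64 for Ccnb2, 2.48 for Cdca3, 2.81 for Spc24 and 2.36 for the clock and hypoxia gene Bhlhe40. Between immature and proBpreB cells it was -1.86 for 2810417H13Rik, -2.06 for Esco2, -2.17 for Casc5 and -1.78 for Cdca3, and also 3.12 for Smtnl2 and 2.25 for Aldoc. Between mature and proBpreB cells it was 3.03 for Ndrg1, 3.90 for Smtnl2, 2.50 for Egln3, 1.62 for Pfkfb3, 2.42 for Tmem26, 1.84 for Atp1b1, 4.18 for Plod2 and 3.08 for Vegfa. The 3 comparisons called 1395, 995 and 393 genes in the order immature against proBpreB, mature against immature and mature against proBpreB. Vhl itself was lowered to unlike degrees, to 40.1% of the flox/WT mean in proBpreB, 15.7% in immature and 26.1% in mature cells. Differences between populations cannot be told apart from this difference in Vhl.

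List medians differed as follows by camera. Between immature and proBpreB cells the median differences were 0.41 for other hypoxia genes, -1.54 for proliferation (adjusted p = 0.0700 with an estimated correlation), -0.45 for cholesterol synthesis (adjusted p = 0.174 with an estimated correlation) and 0.37 for neutrophil and monocyte markers (adjusted p = 0.884 with an estimated correlation). Between mature and immature cells they were 2.15 for proliferation and 0.46 for the Bcl2 family (adjusted p = 0.174 with an estimated correlation). Between mature and proBpreB cells they were 0.29 for other hypoxia genes, 0.16 for HIF pathway components (adjusted p = 0.0700 with an estimated correlation), 0.57 for pro-B and pre-B genes (0.360), 0.64 for proliferation (0.724), -0.20 for cholesterol synthesis (0.724) and -0.44 for the interferon response (0.884).

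The first pattern weighed was the fall of proliferation genes in immature flox/flox cells. A lower share of cycling proBpreB cells in that sort would need a median of 34.7% of proBpreB cells in the flox/WT sort (95% bootstrap interval 26.7 to 42.9), whereas the share that each of 20 pro-B and pre-B genes allows there had a median of 9.09% (2.78 to 19.8), which argues against it as the whole cause. This was the last of 3 versions: the first compared a median log2 change of 0.78 (-0.01 to 0.99) with 0 and left it open, and the second, with intervals over genes alone (3.01 to 19.7 against 29.0 to 38.9), excluded it. A cycling subset of pre-B cells with few of these transcripts was not tested and may still contribute. A difference in cycling of the immature cells themselves stays open as a hypothesis.

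The second pattern was the rise of proliferation genes in mature flox/flox cells. For proBpreB cells in that sort, pro-B and pre-B genes implied a median share of 2.07% (0.677 to 3.20) and proliferation genes 6.79% (2.56 to 10.5), and as the intervals overlap, such cells cannot be told apart from a change in mature cells. An earlier version of this test, with intervals over genes alone (1.11 to 2.89 against 4.97 to 7.55), had excluded them, and the wider interval was kept. Immature cells in the sort would have to make up a median of 129% (74.3 to 334) to account for the proliferation genes. The 5 genes high in immature cells implied 6.54% (2.78 to 36.4), too little by that set for such cells to be the whole cause. That was 1 of 5 versions. A level difference of 0.14 decided nothing. The 3 other gene sets gave 63.2% (51.8 to 88.1), 35.6% (4.81 to 109) and 9.87% (3.25 to 15.7). The first and second of these were set against an interval of 123 to 153 over genes alone. Both reach past 74.3, the lower bound over genes and libraries, so the answer depends on the gene set and stays open.

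Of 35 splits of the 8 mice into 4 and 4, the real split alone, 1 of 35, gave as many genes in each genotype comparison. The same held for each difference of genotype effects. That share is the smallest that 35 splits can give. The other splits mix the genotypes within a group, so a genotype effect widens their spread and lowers their counts. They also remove the effect that the populations share, so they are no separate test of the differences. The highest of the other splits called 1 gene in proBpreB (788 in the real split), 137 in immature (2656) and 51 in mature cells (2096). For the differences it called 2 (1395), 6 (995) and 1 (393). For the stages, 8 splits part the libraries of all 4 mice, too few for a share under 0.05. The real splits called 6350, 4207, 7188 and 3411 genes, and the highest others 311, 77, 0 and 1, in the order immature against proBpreB and mature against immature in flox/WT mice, then the same in flox/flox mice. Splits that part fewer mice called at most 77, 7, 1 and 85 genes.

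In 4 of 156 groups of 4 libraries 1 library lay far from the others, where chance gives about 5%. For HIF pathway components the mean log2 CPM was 5.33 in immature flox/flox replicate 1 (others 5.60 to 5.63) and 4.91 in mature flox/WT replicate 3 (4.74 to 4.76). For cholesterol synthesis it was 4.54 in immature flox/WT replicate 1 (4.74 to 4.77), and for trafficking genes 6.41 in immature flox/flox replicate 1 (6.54 to 6.57).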

How the results depend on the processing

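All alternatives were planned except the sex of the mouse as a covariate, which was chosen after seeing the data. None of the named genes turned direction in a setting that gave it a value: 4598 values kept their call and 140 lost it. Genes below a setting's filter had no value there. That left out 12 values with the filter of 10 CPM and 2 with only the groups compared. A gene named in several comparisons counts in each, as Hif3a did with the first filter in the 3 populations. T cell and sex-linked lists had no value in these settings respectively. Of the list values 965 kept their call, 27 gained it, 53 lost it and 53 turned the sign of the median, and the lists that turned had no camera call. That count depends on the definition of a turn, which was changed after first results: with lists uncalled in both settings counted as kept it is none, and the sign of the median is used here. By fry, which tests against no change and not against the other genes, 3 list calls were lost and 7 gained. RLE size factors moved no median by over 0.1. The planned setting without immunoglobulin genes had nothing to remove and was not run.

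The mature genotype count was 1296 with only the groups compared in the fit, and the mature against proBpreB difference 606 with DESeq2. The causes were not tested. With an estimated correlation 7 in place of 29 list tests passed. The estimates were 0.60 for proliferation, 0.41 for oxidative phosphorylation and 0.031 for natural killer markers, against the preset 0.01. How far this accounts for each lost call was not tested. With 1 mouse left out, the genotype counts ranged from 466 to 1015 in proBpreB, 2039 to 2848 in immature and 1482 to 2393 in mature cells. The differences between populations ranged from 805 to 1807, 661 to 1129 and 254 to 444, the stage counts from 5408 to 6392, 3295 to 4236, 6123 to 7395 and 2528 to 3661, and the list tests from 25 to 30.

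With the replicate number as a block the genotype counts were 898, 2850 and 2301. Mice of different genotypes share only a number: their deviations correlated at -0.302 to 0.544, 5 of 12 over 0.1 and 5 highest for their own number. With the mouse as a block the counts of the stages were 6588, 4436, 7334 and 3633 and those of the differences 1559, 1088 and 484. With the replicate number 29 list tests passed, and no blocked count moved by over 1.5 times.

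Medians that turned sign had no stable direction, and except for the sex-linked list the cause was not tested. That list holds Xist and Y-linked genes, and only replicate 1 of each genotype had Y-linked counts above Xist. Leaving out either of these mice removes nearly all Y-linked counts from its genotype, which sets the sign of that median. HIF pathway components in proBpreB were at -0.042 with the filter of 10 CPM and -0.027 with only the groups compared. Stroma markers were at 0.13 in proBpreB and 0.28 in mature cells without a filter. Plasmacytoid dendritic cell markers were at -6e-04 in immature and -0.0092 in mature cells with sex as a covariate. With 1 mouse left out, proBpreB medians ranged from -0.077 to 0.068 for HIF components, -0.056 to 0.19 for pro-B and pre-B genes, -0.27 to 0.064 for the Bcl2 family, -0.030 to 0.13 for proliferation, -0.023 to 4e-04 for cholesterol synthesis, -0.011 to 0.12 for neutrophil, -0.33 to 0.44 for stroma and -8.11 to 9.38 for sex-linked genes. Immature medians ranged from -0.095 to 0.029 for trafficking, -0.057 to 0.069 for the unfolded protein response, -0.13 to 0.16 for immediate early, -0.21 to 0.018 for plasma cell, -0.20 to 0.39 for dendritic cell and -9.72 to 7.36 for sex-linked genes. Mature medians ranged from -0.021 to 0.48 for the Bcl2 family, -0.041 to 0.35 for immediate early, -0.053 to 0.52 for T cell, -0.22 to 0.22 for dendritic cell, -0.18 to 0.23 for stroma and -7.37 to 9.85 for sex-linked genes. At this depth, with totals from 7850186 counts, small changes were often missed in the simulation. Its runs called 144, 141 and 131 genes between genotypes, against 788, 2656 and 2096 in the data. Fewer calls make the adjusted threshold stricter, so the share missed in the data was not measured.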

Other observations

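The 12 tests of 4 gene groups in this part were chosen after changes of some of their members were seen in these libraries. Their p-values do not cover that choice, so whether each group changed as a whole stays open. By contrast, the test of later-stage cells was fixed before its result was seen.

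Members of glycogen metabolism and of the circadian clock rose in flox/flox cells of the 3 populations. Of 15 glycogen genes, 6 rose in proBpreB, 9 in immature and 8 in mature cells, with median log2 changes of 0.24, 0.63 and 0.67 (camera with an estimated correlation, adjusted p = 0.000191 for each over the 12 tests). Gys1, glycogen synthase, rose by 1.19, 1.64 and 1.46, and the branching enzyme Gbe1 by 1.17, 1.63 and 1.78. Of 16 clock genes, 6, 8 and 8 rose and 1 fell in immature cells, with medians of 0.43, 0.61 and 0.51 (adjusted p = 0.000191, 0.00113 and 0.000191 with an estimated correlation). Ciart, a repressor in the clock, rose by 5.43, 6.23 and 5.45. Arntl, Clock, Cry1 and Per3 passed in no population, and the clock gene that fell in immature cells was Nr1d2, at -0.78. Bhlhe40, also a member of a list fixed in advance, rose by 1.65 in proBpreB and 2.50 in mature cells and measured 0.14 without a call in immature cells.

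For lysine demethylases of the JmjC family, camera's call with an estimated correlation held in immature cells and was lost in proBpreB and mature cells, and for replication-dependent histone genes it was lost in the 3 populations. Of 18 demethylases, 3 of them in lists fixed in advance, 6, 8 and 7 rose and 1 fell in immature cells, with medians of 0.066, 0.30 and 0.096 (adjusted p = 0.0934, 0.0280 and 0.115 with an estimated correlation). Kdm5b rose by 1.27, 2.66 and 2.13. Of 64 histone genes, 11, 17 and 12 fell and 2 rose in immature cells, with medians of -0.73, -0.69 and -0.53 (adjusted p = 0.0839, 0.211 and 0.211 with an estimated correlation). Histone genes are near-identical copies, so these values are uncertain. Some copies gave the same values. Hist2h2aa1 and Hist2h2aa2, the 2 that rose in immature cells, both measured 0.89 (SE 0.29, edgeR adjusted p = 0.0297). Such copies, also found among the genes that fell, are not separate results, so the counts of changed genes overstate them.

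The third pattern weighed was the fall of mature B cell genes in proBpreB flox/flox cells. If fewer later-stage cells in that sort were the cause, genes at 16-fold or more in immature over proBpreB cells should fall by as much as the list, whose median was -0.54. Their median was -0.58 (95% bootstrap interval -0.90 to -0.29, 19 genes, 15 lower), so fewer such cells and a lower expression per cell cannot be told apart. Members of the mature B cell list, such as Ms4a1, were kept among the 19 genes, so part of the agreement of the medians was built in.

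Y-linked counts exceeded Xist in 1 flox/flox and 1 flox/WT mouse, and the 3 libraries of each of the 8 mice gave the same sex. Counts of Hba-a1 and Hba-a2 were equal in 21 of 24 libraries.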
